A study of Homo sapiens with 20 samples.

How the data were processed

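RNA from cultures of Calu-3 cells, a human airway epithelial line derived from a lung adenocarcinoma, was measured on 20 one-colour (Cy3) Agilent whole-genome arrays with 41000 probes that are not controls. Each array holds 1 treatment at 1 time. Per the labels' series design, each array carries cDNA pooled from 3 experiments and no treatment and time was hybridised more than 1 time, so no array has a biological replicate. The arrays lie on 5 slides of 4 arrays, as read from the file headers.

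Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 9.5.3.1. The deposited processed signal is an intensity: per the file headers, the local background was subtracted, spatial and multiplicative trends were removed, low values were replaced by a surrogate, and the arrays were not normalised to one another. The deposited series table holds log2 values. Its header gives no method, but the values themselves follow a simple rule: log2 of the processed signal minus the 75th percentile of the array, then minus the median of the probe over the 20 arrays. Values rebuilt by that rule differed from the deposited log2 values by a median of 0.0009, and 99.71% of them lay within 0.01.

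The values used here are log2 of the processed signal minus the 75th percentile of each array, without the centring of probes. Of the 41000 probes, 264 were spotted 10 times, and the mean of log2 signal over their spots was taken, without spots that Feature Extraction marked as uneven or as outliers. The standard deviation of log2 signal over repeated spots ranged from 0.043 to 0.071 between arrays, which is technical precision within an array and not variation between cultures. The share of probes well above background, as Feature Extraction calls it, ranged from 67.9% to 81.0%, and 26449 probes were well above background on all arrays.

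Gene names came from the RefSeq accession or symbol that the files pair with a probe, looked up in a RefSeq gene table. In total 27066 probes received a name, 23371 by accession, 2312 by current symbol, 1037 by an older symbol and 346 by the file's own symbol only, and they cover 17717 genes. Another 13860 probes had no name and were tested and counted without being named. Probes for XIST and Y-linked genes, 74 in all, were left out of every step. For a gene with several probes, the probe with the highest mean signal was used. A feature is 1 such gene or 1 unnamed probe, and it entered a comparison when it was well above background on at least 50% of the arrays in it.

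Treatments were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with time as a block, so that the estimate is the mean difference over the matched times and its standard error reflects how far that difference varied between times. Tests are two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The comparisons were neutrophil migration with the chemoattractant fMLP against fMLP alone (5 matched times), anti-CD47 pretreatment against migration without it (4), fMLP against untreated (2), migration against untreated (2), anti-CD47 against fMLP alone (3), and the early (90 min and 4 h) against the late (24, 48 and 72 h) effect of migration. At 4 and 24 h, the times with all 4 treatments, features that differed by at least 1 log2 unit in one direction from both the fMLP and the untreated array were counted without a test. The same count was made for each of the 0 h arrays against the other two.

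Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry (its directional test, and its mixed test, which ignores direction), for lists with at least 5 measured genes. The lists were neutrophil, monocyte macrophage, lymphocyte, erythrocyte and platelet, NF-kB and neutrophil chemokine, immediate early and MAPK feedback, EGFR ligands and wound repair, Wnt beta-catenin target, TGF-beta target, cell cycle and proliferation, NRF2 oxidative stress, unfolded protein and amino acid stress, heat shock, interferon response, hypoxia and glycolysis, sterol synthesis, metallothionein, cell junction, airway secretory and ion transport, p53 target and CD47 axis. At single times the median difference of a list was placed among 10000 random lists of the same size matched on mean signal, as a description of those arrays.

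The genes named in the text were those past the threshold with one sign at every matched time (up to 10 up and 10 down), filled to 10 with the genes of smallest p where fewer passed; the 5 up and 5 down for early against late where any passed; the largest 10 up and 10 down of the single-time counts for migration and 5 and 5 for anti-CD47; up to 4 members of each list with the largest difference in the first 2 comparisons; and CD47, SIRPA and THBS1. Any other gene is said to have been chosen after its values were seen. Where a gene was not well above background on any array of one group, the difference is a lower bound, computed per array against the lowest value of any probe called well above background on that array, and is written as at least N-fold.

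The tests were tested on simulated data with the same designs. In migration against fMLP, over 22653 features, 61.2% of features changed 1.5-fold were recovered, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold. In anti-CD47 against migration, over 23392 features, 26.9%, 62.7% and 90.9% were recovered at these folds. In both comparisons over 2 matched times no changed feature was recovered at any fold (23507 features for fMLP and 22875 for migration, each against untreated). In anti-CD47 against fMLP, over 23362 features, 40.9% were recovered at 4-fold and none at the smaller folds, and in early against late, over 22653 features, 20.9% at 2-fold and 83.3% at 4-fold. A list shifted by simulation in the first 2 comparisons passed with the preset (adjusted p = 5.1e-49 and 1.77e-33) and with the estimated correlation (adjusted p = 0.00591 and 0.0144). The simulated genes varied independently around their means, which real arrays need not do. The shifted list was cell cycle and proliferation, and the shift was larger than its real medians of 0.22 and −0.11. The estimated correlation of its real members was 0.7 and 0.929. These passes therefore do not measure how well the estimated correlation detects the real list differences. Each simulated change was equal at every matched time, or at both early times for early against late. Recovery of changes present at only some of the matched times was not measured.

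Alternatives covered background correction with normexp (offset 50) and quantile normalisation, quantile normalisation alone, scaling by the median of probes above background on all arrays, the deposited log2 values, no filter and a stricter filter on dim probes, the mean over the probes of a gene, eBayes with trend and robust options, each matched time left out, 1 additive fit over 17 arrays, the 0 h pair added, the 90 min pair (the only pair on different slides) left out, other boundaries of early and late, 1.5-fold and 3-fold size rules, and single comparators. After the data had been seen, 2 alternatives were added: migration against fMLP with the 90 min, 4 h and 24 h pairs only, and anti-CD47 against migration without the features that set the 48 and 72 h arrays apart. Other tools were data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.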

Results

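Gene expression was measured in Calu-3 cells, a human lung adenocarcinoma line that forms polarised airway epithelium, grown on the undersurface of porous inserts. Neutrophils (PMN) placed above the insert crossed the epithelium for 90 min towards fMLP, a bacterial-type formyl peptide that attracts them, and the epithelial cultures then recovered in medium. The 20 arrays fall into 4 treatments: untreated (0 h, 4 h and 24 h), fMLP alone (90 min, then 4, 24, 48 and 72 h of recovery), fMLP with migrating PMN (0 h, 90 min, then 2, 4, 24, 48 and 72 h), and the same after pretreatment of the epithelium with a neutralising antibody to CD47 (0 h, 90 min, then 2, 4 and 24 h). CD47 is a surface protein of epithelium and leukocytes that binds SIRPA and thrombospondin 1. Each treatment and time is 1 array, so differences at a single time have no replicate check, and errors below are standard errors over matched times. The arrays had 67.9% to 81.0% of probes well above background and a 75th percentile of processed signal of 575.3 to 1068.4. All differences are on the log2 scale.

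The comparison of fMLP with PMN against fMLP alone asks what neutrophil passage itself did to the epithelium. Over 5 matched times, genes of the cell cycle and proliferation list were higher as a group: all 42 measured members had a higher mean with PMN, with a median difference of 0.22. Without the 90 min pair, the only pair on different slides, the median was 0.12 with 37 of 42 higher. This call and the other list calls below did not hold with an estimated correlation (adjusted p = 0.809 for each of the 4). MKI67, a proliferation marker, was higher by 0.48 ± 0.13 (n = 5 times), the spindle checkpoint kinase BUB1B by 0.50 ± 0.12, and the mitotic kinesins KIF11 and CENPE by 0.41 ± 0.09 and 0.40 ± 0.11. The airway secretory and ion transport list was lower, with 7 of 29 members higher and a median of −0.12. AGR3, an endoplasmic reticulum protein, differed by −0.66 ± 0.10, the secretoglobin SCGB3A1 by −0.57 ± 0.08, the water and glycerol channel AQP3 by −0.43 ± 0.10 and the epithelial sodium channel subunit SCNN1A by −0.34 ± 0.05, each lower at all 5 times. The NF-kB and neutrophil chemokine list was higher (23 of 28 members higher, median 0.27), and so was the erythrocyte and platelet list (8 of 10, median 0.29), in which the haemoglobin genes HBB, HBA1 and HBA2 were higher at all 5 times by 1.31 ± 0.25, 0.69 ± 0.14 and 0.68 ± 0.15. The 0 h array of fMLP with PMN already differed from the untreated 0 h array in cell cycle genes (36 of 42 higher, median 0.24) and airway secretory genes (28 of 30 lower, median −0.29), by as much or more.

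Camera with the preset correlation gave these lists adjusted p of 2.05e-08 for cell cycle, 0.00116 for airway secretory, and 0.048 for each of NF-kB and erythrocyte and platelet. Fry's directional test called none (lowest adjusted p = 0.154), and its mixed test, which ignores direction, called 11 of 20 lists. Leaving out the 90 min pair left 2 lists called, cell cycle and airway secretory (adjusted p = 0.000142 and 0.00116). Without 4 h or without 48 h NF-kB was no longer called, and without 24 h erythrocyte and platelet was not. Interferon genes were called higher without 4 h (median 0.28, adjusted p = 0.00306) and lower without 72 h (median −0.10, adjusted p = 0.00144), when 9 lists were called in all. For single genes, limma called 0 of 22653 features, with a lowest adjusted p of 0.156. At an unadjusted p under 0.05 there were 4241 features (2371 higher, 1870 lower), where 1133 are expected by chance. After quantile normalisation the larger share was lower (1954 higher, 2090 lower). The same test with trend and robust options called 287, and 1 additive fit over 17 arrays called 13. Adjusted over the list alone, 10 airway secretory genes, 6 erythrocyte and platelet genes, 3 monocyte macrophage genes, 2 lymphocyte genes and 1 neutrophil gene (TYROBP, an adaptor of myeloid receptors, 0.62 ± 0.10) passed, and 0 of the cell cycle or NF-kB genes.

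The genes of smallest p, none of which passed, were RETN, coding for resistin, a product of myeloid cells (0.85 ± 0.10), GZMA, a granzyme of cytotoxic lymphocytes (−1.14 ± 0.13, well above background on 2 of 5 arrays with PMN and 5 of 5 without), KRTAP3-1 (0.56 ± 0.07), the complement regulator C4BPA (−0.43 ± 0.06), SCGB3A1, DBF4B (0.47 ± 0.07), GRAP (0.56 ± 0.08), RAB1A, a GTPase of transport from endoplasmic reticulum to Golgi (−0.35 ± 0.05), GZMH (0.42 ± 0.06) and the carboxypeptidase CPVL (−0.38 ± 0.06). Each had an adjusted p of 0.156 and 1 sign at all 5 times. CD47 differed by −0.34 ± 0.10 and its ligand THBS1 by 0.34 ± 0.16, and for SIRPA the 2 probes disagreed in sign (−0.07 and 0.09). The remaining lists did not pass. Their median differences were 0.09 for neutrophil, 0.14 for monocyte macrophage, 0.04 for lymphocyte, 0.07 for immediate early and MAPK feedback, 0.08 for EGFR ligands and wound repair, 0.06 for Wnt beta-catenin target, 0.11 for TGF-beta target, 0.07 for NRF2 oxidative stress, 0.00 for unfolded protein and amino acid stress, −0.01 for heat shock, 0.17 for interferon response, −0.02 for hypoxia and glycolysis, 0.06 for sterol synthesis, 0.15 for metallothionein, 0.01 for cell junction and 0.05 for p53 target. For monocyte macrophage and cell junction the median was positive while the test pointed down, and for hypoxia and glycolysis the median was negative and the mean positive (0.01). Only 22 of the 40 neutrophil genes entered this fit. The filter on dim probes took out genes above background on few arrays, such as SRGN (7 of 20 arrays) and AQP9 (4), so the neutrophil median does not cover them.

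**Figure D1:**
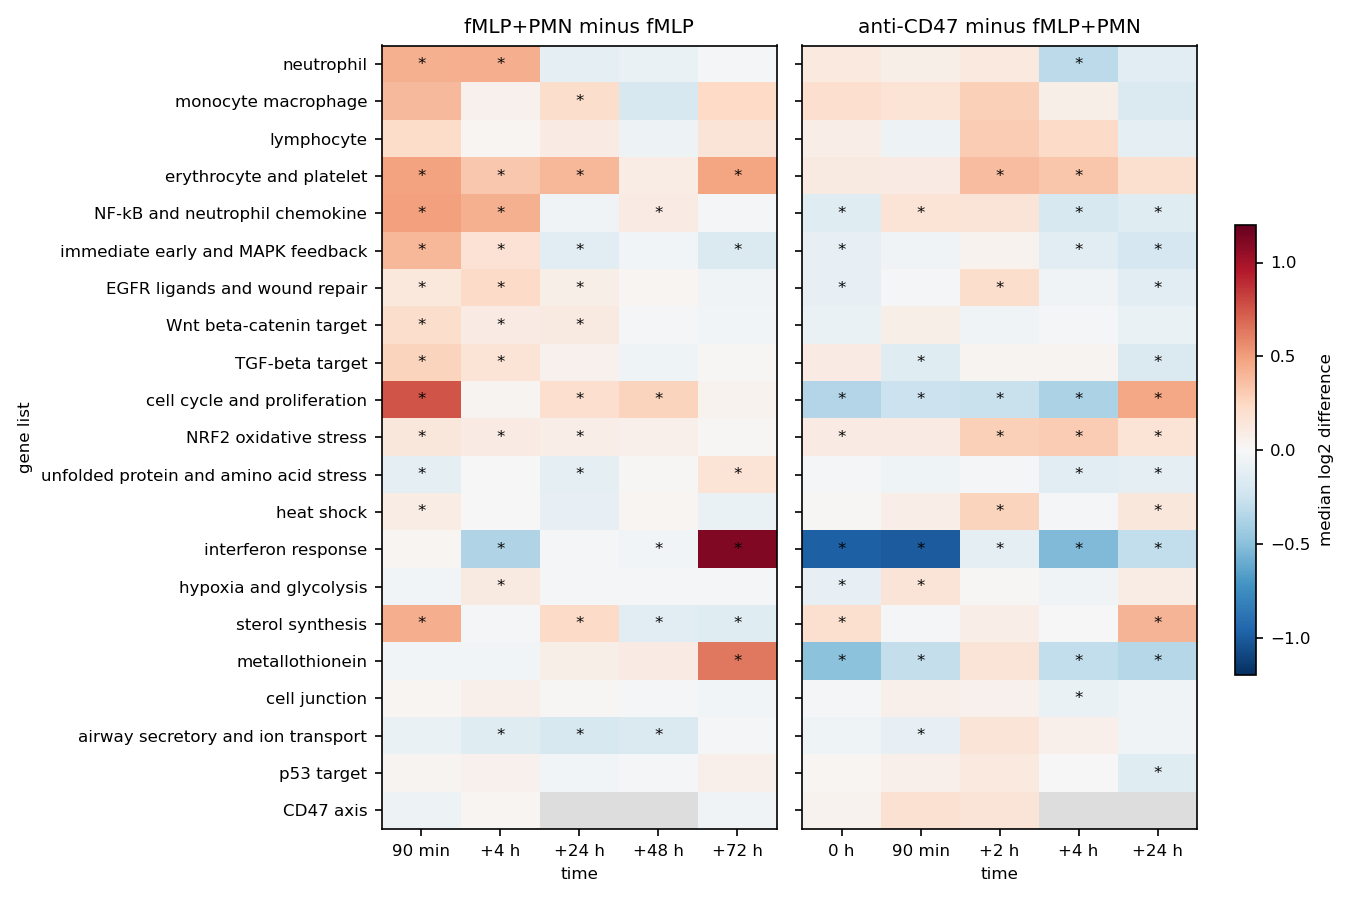
Median log2 difference of each fixed gene list (rows) in each pair of arrays at 1 time (columns), where red is higher and blue lower in the first-named treatment, grey marks lists with under 5 measured genes, and stars mark medians outside the middle 95% of random lists. NF-kB, immediate early and neutrophil lists are red with PMN against fMLP at 90 min and 4 h, and the interferon row is blue in every column of anti-CD47 against fMLP with PMN.

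List medians differed between early and late times, although the test of early against late called no gene and its list calls did not hold with an estimated correlation. At 90 min and at 4 h of recovery the NF-kB and neutrophil chemokine list stood 0.49 and 0.43 above fMLP alone, outside the middle 95% of random lists. At 24, 48 and 72 h its median was −0.04, 0.10 and −0.02. Many lists left the middle 95%: of 21, 11 lay above and 1 below it at 90 min, and 9 and 2 at 4 h. At 0 h, fMLP with PMN against untreated put 3 above and 5 below. TNFAIP3, a feedback inhibitor of NF-kB, averaged 0.75 ± 0.21 over the 5 times. CXCL8, a chemokine that attracts neutrophils, differed by 2.81 at 90 min and −0.54 at 72 h, and CCL20, which attracts dendritic cells and lymphocytes, by 2.80 at 90 min and −0.45 at 24 h. Immediate early genes (0.40 and 0.17, then −0.14, −0.03 and −0.17) and neutrophil genes (0.43 and 0.44, then −0.12, −0.08 and −0.01) followed the same order. S100A8, a calcium-binding protein abundant in neutrophils, stood at 2.05 and 2.49 and then 0.17, 0.21 and −0.22. The interferon response list had medians of 0.02, −0.36, −0.01 and −0.03 up to 48 h and 1.11 at 72 h, where MX1 and CXCL10 stood at 2.11 and 2.68. Cell cycle medians were 0.75 at 90 min and 0.03, 0.20, 0.27 and 0.04 after it. Metallothionein genes, which bind zinc and copper, had their largest median, 0.63, at 72 h too.

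The test of early against late times called 0 of 22653 features with limma (1338 at an unadjusted p under 0.05, with 1133 expected by chance, lowest adjusted p 0.598). The same count was 1 after quantile normalisation, which also moved the split of features at p under 0.05 from 915 higher and 423 lower to 758 and 672. Chosen after their values were seen, the genes of smallest p included S100A8 (early minus late 2.22 ± 0.20), the cytokine gene OSM (1.79 ± 0.21) and the chemokine receptor gene CXCR4 (0.85 ± 0.13), with adjusted p of 0.598, 0.655 and 0.729. List tests of this difference, also chosen after, gave higher early effects for NF-kB (median 0.66, adjusted p = 7.93e-08), immediate early (0.35, 1.18e-09) and neutrophil genes (0.28, 4.69e-06) and a lower one for interferon genes (−0.55, 7.93e-08), whose late medians lay over 0.1 from 0 at 72 h only. TGF-beta target (0.27, 0.00213), cell cycle (0.22, 0.00289), sterol synthesis (0.25, 0.00289), EGFR ligand (0.16, 0.00867) and erythrocyte and platelet genes (0.22, 0.0108) had higher early effects and metallothionein genes a lower one (−0.25, 0.00289). With an estimated correlation none held (lowest adjusted p = 0.204), and the directional fry test called none (lowest adjusted p = 0.0543).

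**Figure D2:**
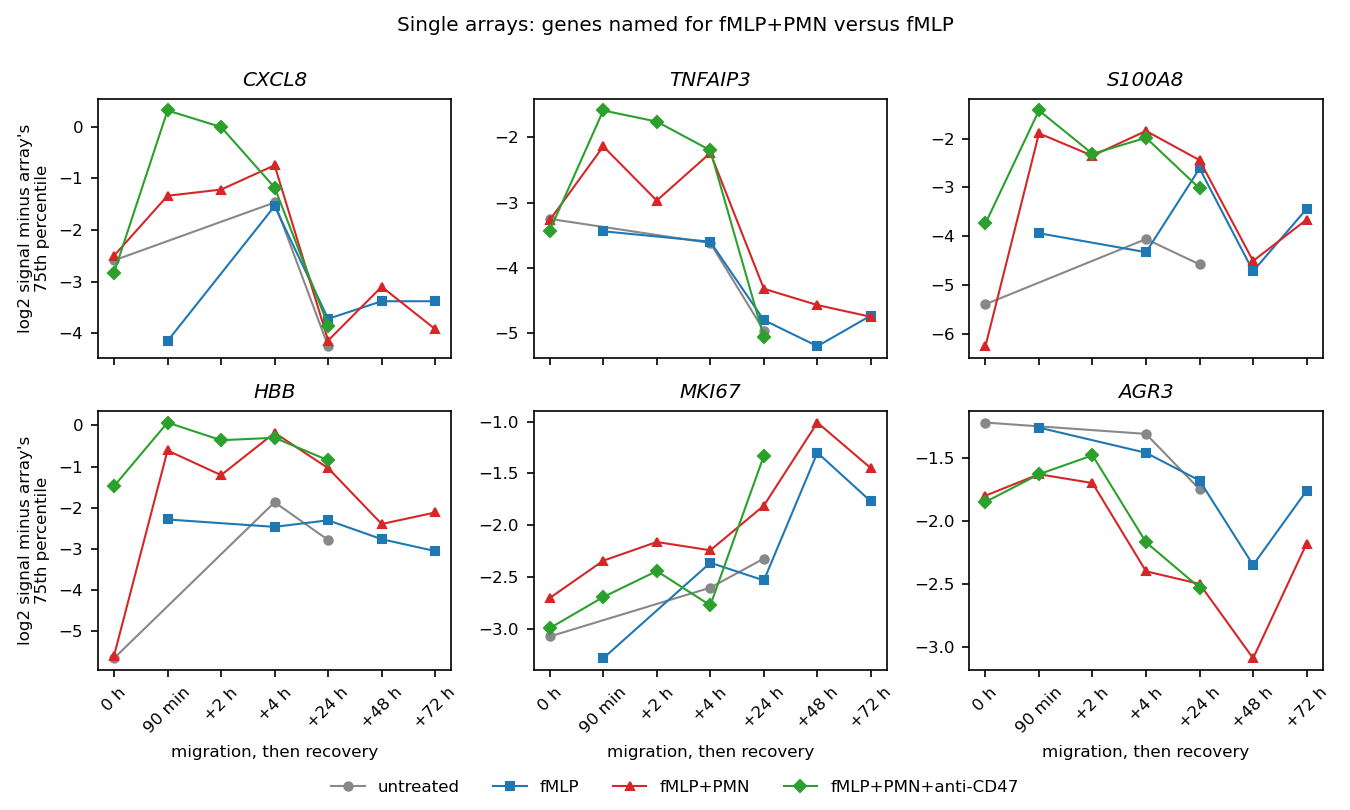
Log2 signal relative to each array's 75th percentile over time (90 min of migration, then hours of recovery) for CXCL8, TNFAIP3, S100A8, HBB, MKI67 and AGR3, with 1 point per array and 1 line per treatment. CXCL8, TNFAIP3 and S100A8 lie above the fMLP line at 90 min and 4 h and differ less from it at the later times, whereas HBB lies above and AGR3 below the fMLP line at all 5 matched times.

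The comparison of anti-CD47 with fMLP and PMN without the antibody addresses the antibody pretreatment, with no control antibody. CD69, an early activation antigen known best from lymphocytes, was higher by 2.61 ± 0.09 (n = 4 times, range 2.38 to 2.74, adjusted p = 0.0068). It was well above background on 4 of 4 anti-CD47 arrays and 0 of 4 arrays without antibody, so the difference is at least 2.00-fold. CD69 was already higher at 0 h, by 3.35 against fMLP with PMN and 3.22 against untreated. These 0 h values are not exact, because CD69 was dim there without antibody. Interferon response genes were lower as a group, with 0 of 35 members higher and a median of −0.44. None of the 5 list calls here held with an estimated correlation (lowest adjusted p = 0.927). BST2, which tethers enveloped viruses, differed by −1.17 ± 0.19, IFI6 by −0.92 ± 0.16, IFITM1 by −0.91 ± 0.16 and IFI44L by −0.86 ± 0.13. Antioxidant genes of the NRF2 oxidative stress list were higher (22 of 25, median 0.23), including the glutathione peroxidase GPX2 by 0.58 ± 0.07, and so were sterol synthesis genes (22 of 25, median 0.15), with the isomerase IDI1 at 0.37 ± 0.10 and list medians of −0.01, 0.08, 0.00 and 0.41 at 90 min, 2, 4 and 24 h. Cell cycle genes (7 of 43 higher, median −0.11) and immediate early genes (10 of 32 higher, median −0.10, with the stress factor ATF3 at −0.79 ± 0.22) were lower over the 4 times, cell cycle genes with the opposite sign at 24 h (median 0.46).

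Other differences were large and had 1 sign at all 4 times without passing over all genes. The acute phase protein SAA1 differed by −1.80 ± 0.11 and the anthrax toxin receptor ANTXR1 by −1.26 ± 0.08 (adjusted p = 0.0536 for both), ANXA10 by 1.15 ± 0.08 and the intestinal lectin LGALS4 by 1.19 ± 0.08 (adjusted p = 0.0656), and SERPINA1, coding for alpha-1 antitrypsin, by 1.09 ± 0.09, SALL4 by 1.08 ± 0.09, transthyretin (TTR) by 1.53 ± 0.14 and RDH12, well above background on 2 of 4 arrays without antibody, by 1.57 ± 0.15 (adjusted p = 0.0887). GNAZ had 0.99 ± 0.09 on the probe used and −0.17 on its other probe. Chemokines moved apart: CCL20 was higher by 2.30 ± 0.27 and CCL2, which attracts monocytes, lower, at −1.51 ± 0.22. The collagenase MMP1 was higher by 2.35 ± 0.37 and the hyaluronan receptor CD44 by 0.77 ± 0.09, while KRT17 differed by −0.75 ± 0.09. Of Wnt targets, the feedback gene AXIN2 differed by −1.16 ± 0.19 on the probe used and −0.03 on its other probe, and the secreted inhibitors FST and DKK1 by 1.5 ± 0.34 and 1.05 ± 0.27. MUC4 and LCN2 differed by −0.94 ± 0.19 and −0.78 ± 0.11 and the secreted scavenger receptor DMBT1 by 1.16 ± 0.28. Among the partners of CD47, SIRPA was higher by 0.75 ± 0.08 (3 probes, from 0.00 to 0.75) and THBS1 differed by −0.72 ± 0.12, and for CD47 itself the probes disagreed (0.23 and −0.08).

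In all, limma called 1 of 23392 features (CD69), 175 had an adjusted p under 0.1, and 4273 had an unadjusted p under 0.05 (2430 higher, 1843 lower) where 1170 are expected. The call depends on the processing: leaving out any 1 time ended it (CD69 adjusted p 0.0666 to 0.155), and background correction with normexp raised the count to 410. Camera gave adjusted p of 1.39e-15 for interferon, 7.89e-05 for NRF2, 0.00974 for sterol synthesis, 0.0153 for cell cycle and 0.0170 for immediate early genes. With an estimated correlation these were 0.927, 0.927, 0.935, 0.935 and 0.935. Fry's directional test called none and its mixed test 15 of 21. Leaving out 90 min or 2 h ended the cell cycle call, leaving out 4 h ended the cell cycle and immediate early calls, and leaving out 24 h ended the sterol and immediate early calls. Cell cycle genes were lower at 90 min, 2 h and 4 h (medians −0.26, −0.27 and −0.38) and higher at 24 h (0.46).

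Adjusted over the list alone, 18 interferon genes passed, 12 EGFR ligand and wound repair genes, 11 airway secretory genes, 5 Wnt target genes, 4 neutrophil genes, 3 NF-kB genes, 3 CD47 axis genes, 2 erythrocyte and platelet genes, 1 TGF-beta target gene (TGFBI, −0.97 ± 0.15) and 1 NRF2 gene (GPX2). The airway secretory genes that passed went both ways, among them DMBT1 up and MUC4 down, and so did the wound repair genes (MMP1 up, KRT17 down), the NF-kB genes (CCL20 up, CCL2 down) and the Wnt genes. The chloride channel gene CFTR, chosen after its values were seen, differed by −0.62 ± 0.09. The 6 genes of the CD47 axis had a median of 0.09. For NF-kB, Wnt target and monocyte macrophage genes the median and the mean differed in sign, and for EGFR ligand and airway secretory genes a positive median stood beside a test that pointed down.

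Differences of the same sign were present on the 0 h arrays, although the labels do not say when these were taken relative to the antibody and to the addition of fMLP and PMN. On the 0 h arrays the interferon median with the antibody was −0.98 against fMLP with PMN, the metallothionein median −0.49 and the cell cycle median −0.35. CD69 was well above background on the 0 h array with the antibody and on neither other 0 h array, and SAA1 stood at −2.08 against fMLP with PMN and −3.41 against untreated. Across 23383 features, the 0 h difference from fMLP with PMN correlated with the mean over the 4 matched times at Pearson r = 0.38 (Spearman rho 0.36), and the 0 h difference from untreated at r = 0.20 (rho 0.11). Genes are not independent replicates, so no p is given. Of the 100 named genes of smallest p, 98 had the same sign at 0 h against fMLP with PMN and 91 against untreated.

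**Figure D3:**
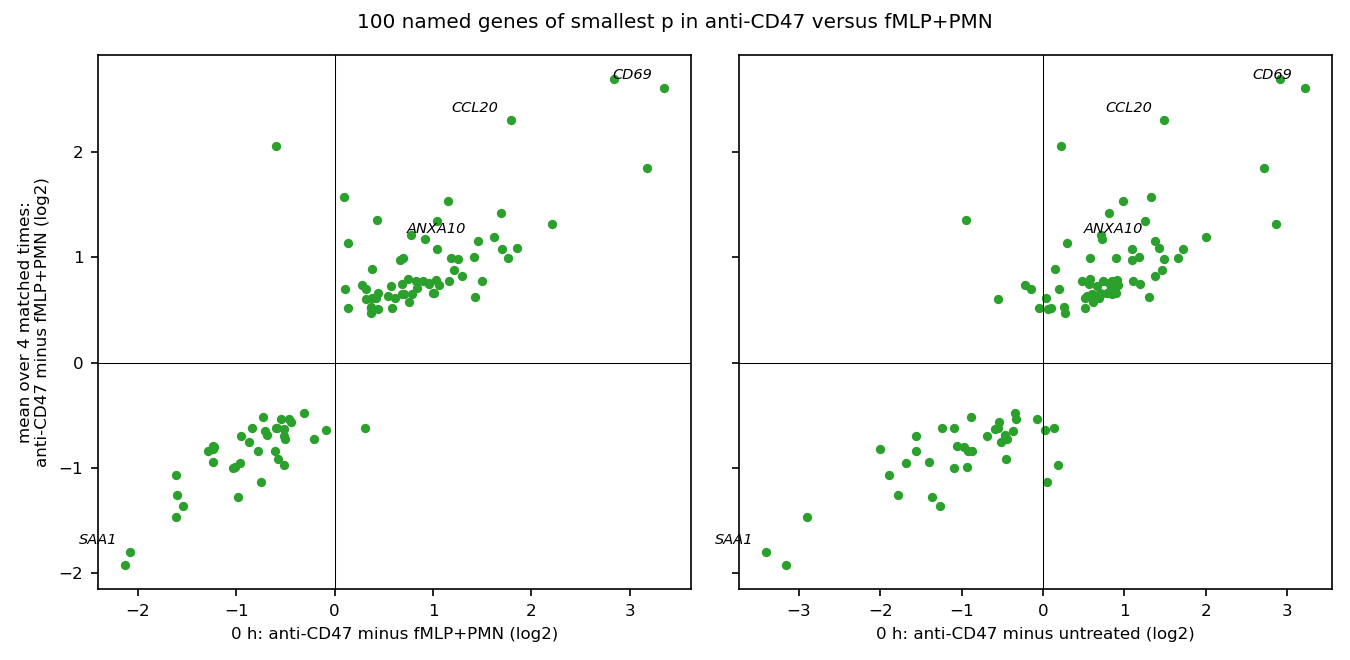
Each point is 1 of the 100 named genes of smallest p in anti-CD47 against fMLP with PMN, with the mean log2 difference over the 4 matched times on one axis and the log2 difference of the 0 h anti-CD47 array on the other, from the fMLP with PMN array at 0 h (left) or the untreated array at 0 h (right). In the left plot 98 of 100 genes have the same sign on both axes and in the right plot 91, and for genes such as CD69 that are not well above background on one of the arrays the difference is not exact.

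CD69, SAA1, ANTXR1, CCL20 and MMP1 also set the 48 and 72 h arrays, with and without PMN, apart from the earlier untreated and fMLP arrays. Earlier arrays with PMN were not part of that choice. For CCL20 they were not all apart: with PMN it stood 2.80 above fMLP alone at 90 min, beside 3.03 for fMLP at 48 and 72 h against 90 min. CD69 stood at −4.31 and −4.17 with fMLP alone at 48 and 72 h and at −4.07 and −4.54 with PMN, and was not well above background on any earlier fMLP array. ANTXR1 was well above background on those (−3.66 to −3.19) and on none of the 4 arrays of 48 and 72 h. Chosen after the values were seen, 218 features (63 higher, 155 lower) lay at least 1 log2 unit beyond every untreated and fMLP array from 90 min to 24 h on all 4 arrays of 48 and 72 h. Of these, 187 (85.8%) lay in the same direction on the 0 h anti-CD47 array against both other 0 h arrays, compared with 17 (7.8%) for the untreated and 14 (6.42%) for the fMLP with PMN array. For each feature only 1 of the 0 h arrays can lie furthest, so these shares are not independent. Features that vary together can also put a large share on 1 array, and no chance level was computed for these shares. CD69, the only called feature, is one of the 218, and 4107 of 23177 features outside the set had an unadjusted p under 0.05. Cell cycle genes went the other way, with a median of 1.43 for fMLP at 48 and 72 h against 90 min and −0.35 on the 0 h anti-CD47 array against fMLP with PMN. That reference array was itself above untreated in these genes, and no median of the anti-CD47 array against untreated is given.

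**Figure D4:**
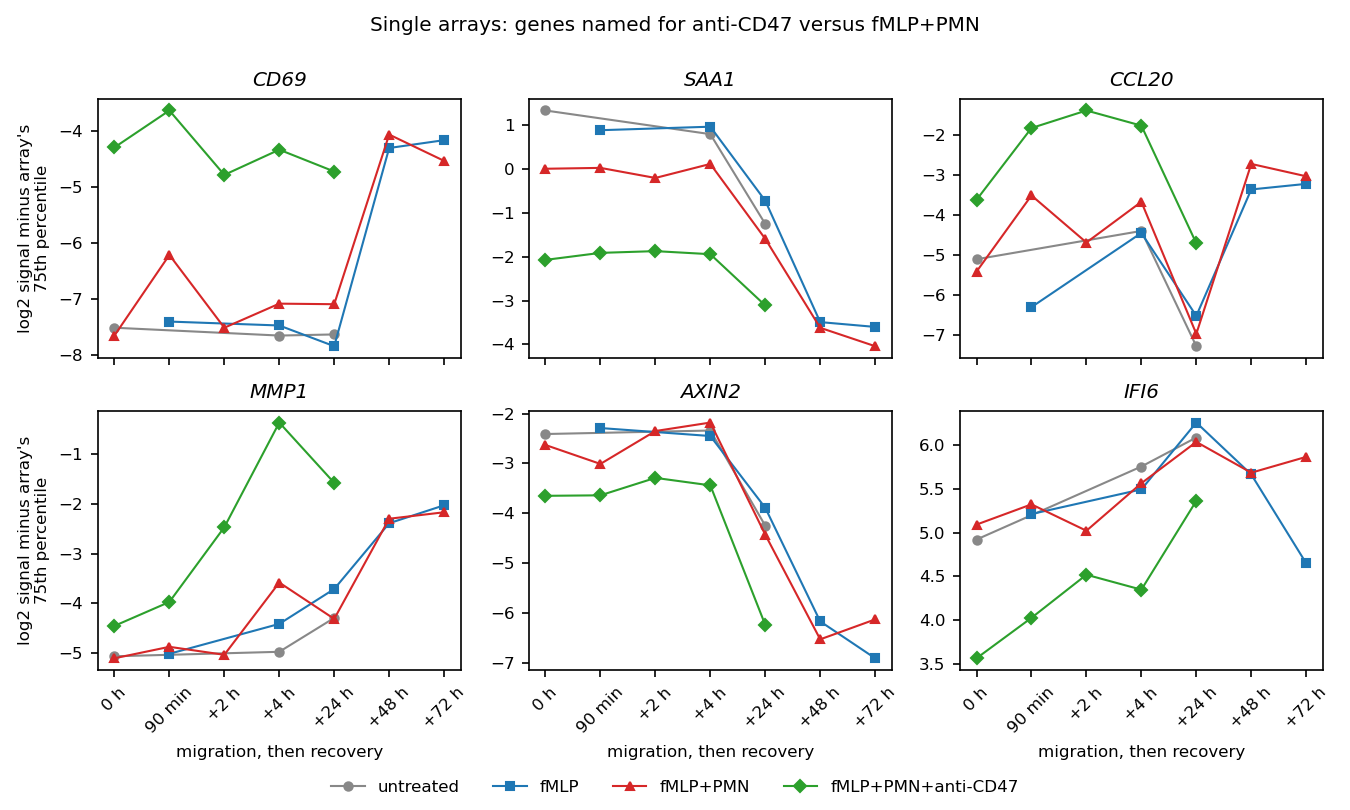
Log2 signal relative to each array's 75th percentile over time for CD69, SAA1, CCL20, MMP1, AXIN2 and IFI6, with 1 point per array and 1 line per treatment. The anti-CD47 line leaves the others at 0 h for CD69, SAA1 and IFI6, and the fMLP and fMLP with PMN lines reach the anti-CD47 level of CD69 at 48 and 72 h.

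The comparison of fMLP with untreated cells, at 4 and 24 h, shows what the peptide did without neutrophils. Interferon response genes were lower as a group, with 1 of 35 members higher and a median of −0.14. Camera gave adjusted p = 5.12e-06, which did not hold with an estimated correlation (adjusted p = 0.914), nor with either fry test, and the medians at the single times were −0.31 at 4 h and 0.01 at 24 h. The other lists did not pass, with neutrophil genes at a median of 0.05 and NF-kB genes at 0.04. The genes of smallest p were dim in one group: KCNK17 and PURG were well above background on both untreated arrays and neither fMLP array (at least 3.96-fold and 2.35-fold lower, adjusted p = 0.135), and SLC4A10 on both fMLP arrays and neither untreated array (at least 4.94-fold higher, adjusted p = 0.209). EGFLAM, MGARP, SCGB1D2 and ZNF829 were lower and SERHL, SLC24A4 and FGF5 higher, with adjusted p of 0.209 to 0.463. Limma called 0 of 23507 features (885 at an unadjusted p under 0.05, 289 higher and 596 lower, with 1175 expected), the trend and robust options called 13, and quantile normalisation moved that split to 415 higher and 385 lower. The differences at the times correlated at −0.02 across features, which are not independent replicates.

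Against untreated cells at the same 2 times, fMLP with PMN shows the peptide and migration together. S100A8 was 2.18 ± 0.11 higher and HBB 1.72 ± 0.11 (adjusted p = 0.412), the defensin gene DEFA3, a neutrophil granule product, was 1.53 ± 0.11 and the lymphocyte antigen gene CD52 1.44 ± 0.14 higher (adjusted p = 0.427), all at both times, with CD52 well above background on 1 of 2 arrays of each group. For S100A8 at 24 h, fMLP alone was already 1.97 above untreated, and fMLP with PMN 0.17 above fMLP. PURG, MYBPC1, SORCS3, ZNF829, HECW2 and SLC38A11 were well above background only on the untreated arrays of this pair and at least 1.02-fold to 1.68-fold lower. Interferon response genes had a median of −0.63 at 4 h and −0.05 at 24 h, and airway secretory genes −0.20 and −0.12. Camera called these lists lower (adjusted p = 8.87e-08 and 0.000912) and neutrophil, NF-kB, EGFR ligand, cell cycle and sterol synthesis genes higher (0.0201, 0.0499, 0.00972, 0.0214 and 0.0309). None held with an estimated correlation (adjusted p = 0.894 for each), and fry called sterol synthesis alone in the directional test (0.0335) and 0 lists in the mixed test. Limma called 0 of 22875 features (2609 at an unadjusted p under 0.05, 1256 higher and 1353 lower, with 1144 expected), and 7 with trend and robust options. That split became 4553 higher and 1220 lower without a filter on dim probes, 1376 and 1251 after quantile normalisation, and 1497 and 2193 with the 0 h pair added. With 2 matched times, 0 of 66 simulated 4-fold changes were recovered in this comparison or the one before it.

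Anti-CD47 with PMN was also set against fMLP alone, at 90 min, 4 h and 24 h. CD69 was 3.34 ± 0.18 higher, which is at least 2.62-fold, and SAA1 lower, at −2.70 ± 0.15 (adjusted p = 0.102 for both). SAA2 differed by −2.14 ± 0.20 and SAA4, well above background on 1 of 3 anti-CD47 arrays, by −2.67 ± 0.27, the class II antigen gene HLA-DPA1 by −1.26 ± 0.12, ANTXR1 by −1.41 ± 0.11, QPCTL (2 of 3 anti-CD47 arrays above background) by −1.53 ± 0.13, DEFA3 by 2.01 ± 0.20, the hyaluronan-binding TNFAIP6 (1 of 3 fMLP arrays above background) by 2.25 ± 0.18 and SERPINA1 by 1.22 ± 0.12 (adjusted p = 0.182). Camera called 8 lists. Interferon (0 of 35 higher, median −0.69, adjusted p = 8.86e-27), metallothionein (−0.33), airway secretory (−0.09) and unfolded protein genes (−0.07) were lower. Sterol synthesis (0.38), erythrocyte and platelet (0.40), NRF2 (0.27) and cell cycle genes (43 of 43 higher, 0.23) were higher. None held with an estimated correlation (lowest adjusted p = 0.378) or with the directional fry test (0.0576), and the mixed fry test called 12 of 20. Limma called 0 of 23362 features (2688 at an unadjusted p under 0.05, 1517 higher and 1171 lower, with 1168 expected). Without the 90 min pair, whose arrays lie on different slides, it called 3, with normexp 123, with trend and robust options 146 and in the additive fit 1275, and quantile normalisation moved the split at p under 0.05 to 1080 higher and 1573 lower.

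At 4 h, 276 of 22800 features on the fMLP with PMN array differed by at least 1 log2 unit in one direction from both the fMLP and the untreated array, 157 higher and 119 lower. Most named ones were dim. S100A8 stood 2.49 and 2.22 above these arrays, and FLJ39743, ERICH6, FGFBP2, TWIST2, ACSM2B, PI16, NGB, PDLIM3 and SULT1A3 were 2.13 or more above both. Brighter genes among the lower ones were FRMD4A, a scaffold of epithelial polarity, at −1.99 and −1.95, and the gel-forming mucin MUC2 at −1.57 and −1.47. GABRR2, COL17A1, GRIK2, OR51A7, IL22RA1, RALYL, COLEC11 and PPP1R14D were not well above background with PMN. At 24 h the count was 197 of 22569 (96 higher, 101 lower, but 69 and 6 among features above background on every array and 25 and 5 with normexp), with BCL6B, ATP6V1B1, MSLNL, BMP5, INGX, GDF9, DKK2, PDE6C, NLRP6 and PDE1A higher, and CD1B, PCDHGB7, ADGRF5, PNLIP, CFHR5, LGALS13, SORCS3, TRIM50, HEY1 and CLIC3 lower and not well above background with PMN.

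For the anti-CD47 array the counts were 374 at 4 h (231 higher, 143 lower) and 468 at 24 h (142 higher, 326 lower). At 4 h MMP1 stood 4.04 and 4.60 above the fMLP and untreated arrays, follistatin (FST) 3.50 and 3.79, and TRIML2, HHLA1 and SRRM4 were also higher, while SAA1 stood at −2.91 and −2.74, SAA4 was at least 5.73-fold and 5.36-fold lower, and GABRR2, MASP1 and PRUNE2 were lower. At 24 h DLK1, CIMIP1, DACT3, TNFSF15, a TNF family cytokine gene, and TWIST2 were higher, and TMEM167B, CD1B, PCDHGB7, CFHR5 and GSTA5 lower, TMEM167B by at least 28.4-fold and 28.3-fold.

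The 0 h arrays show how far arrays differed at the earliest time, which the labels do not place relative to pretreatment or the addition of PMN. By the same rule of size, 147 of 24315 features on the untreated array lay apart from both other 0 h arrays, 133 on the array of fMLP with PMN and 262 on the anti-CD47 array. The 0 h differences had standard deviations of 0.35 (fMLP with PMN minus untreated), 0.40 (anti-CD47 minus untreated) and 0.37 (anti-CD47 minus fMLP with PMN). At 0 h, fMLP with PMN and untreated cells also differed in lists, with medians of −0.29 for airway secretory, 0.24 for cell cycle, −0.23 for NF-kB and −0.22 for interferon genes.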

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

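The tests of the 3 patterns weighed here (anti-CD47 at 0 h, neutrophil genes and cell cycle genes) and the count of splits after normexp were chosen only after the result was seen. A result is listed here when migration moved it one way at both early times (90 min and 4 h) and the other way at all 3 late times (24, 48 and 72 h). The difference between early and late was not tested by this rule, and chance alone gives opposite signs in 6.25% of cases. Neutrophil genes differed by 0.5 between early and late (means of the medians 0.44 and −0.07), immediate early and MAPK feedback genes by 0.4 (0.29 and −0.11), and metallothionein genes by −0.3 (−0.03 and 0.27). The late metallothionein mean rests mostly on the 72 h array. Among named genes, the metallothioneins MT1L and MT1G differed by −0.44 (−0.03 and 0.41) and −0.4 (−0.06 and 0.34). These are 3 of 21 lists, of which 20 were measured at 24 and 48 h, and 2 of 89 genes, and the 2 genes belong to 1 of the lists.

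The anti-CD47 arrays differed from the fMLP with PMN arrays at 0 h as at the later times. An ordinary shift along the culture's time course stays open: the mean difference over the matched times correlated over features at r = 0.34 with fMLP at 48 and 72 h minus 90 min, but at 0.02 with untreated 24 h minus 0 h, and genes are not independent replicates. Cultures of the kind on the 48 and 72 h arrays are a candidate explanation, since 85.8% of the features that set those arrays apart lay towards them on the 0 h anti-CD47 array. That share has no chance level here, because features that vary together can move onto 1 array together. The 7.8% and 6.42% for the other 0 h arrays make up the rest and are no independent control. Lists went both ways. Cell cycle genes were at 1.43 and hypoxia genes at 0.60 on late fMLP arrays against 90 min. On the 0 h anti-CD47 array they were at −0.35 and −0.10 against fMLP with PMN, an array itself above untreated in cell cycle genes. Interferon and metallothionein genes were at −1.24 and −1.63 on late fMLP arrays and were also lower on the 0 h anti-CD47 array. On these values at most part of that state was shared. An effect of the antibody acting before migration cannot be told apart from such cultures, because there is 1 anti-CD47 array at 0 h, no control antibody, and no label of when it was taken.

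Neutrophil genes were higher on fMLP with PMN arrays at 90 min and 4 h, where the list lay at the 99.9th percentile of random lists or above, and at 24 h at the 21.5th. RNA of neutrophils left on the epithelium may account for it. S100A8 stood 2.05 and 2.49 above fMLP alone at the early times, but at 24 h it stood 1.97 higher with fMLP alone than in untreated cells, with no PMN present. Expression of these genes by the Calu-3 cells stays open, because 18 of the 40 listed genes were well above background on every untreated and fMLP array. Another 10 were so on none of those arrays, 4 were so on no array, and 0 belong to another list. Genes above background on all 20 arrays, picked after their values were seen, went from no rise to a clear one. LCP1 stood at 0.03 and 0.08 at 90 min and 4 h and BCL2A1 at 0.07 and 0.08, but FPR1 at 1.05 and 1.04 and FGR at 0.88 and 1.65. The largest rises were in SRGN (3.07 and 4.35) and AQP9 (2.36 and 3.82), above background on 7 and 4 of 20 arrays. Both were dim with fMLP alone, so their differences are not exact.

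Cell cycle genes were higher on fMLP with PMN arrays than on fMLP arrays. Without the 90 min pair, whose arrays lie on different slides, the median went from 0.22 to 0.12 with 37 of 42 members higher. A slide difference of that pair cannot account for what remained, but whether the remainder exceeds chance is not decided. Camera with the preset correlation gave it an adjusted p of 0.000142. The members moved together, with an estimated correlation of 0.7 over all pairs. At that correlation camera gave an adjusted p of 0.809, and directional fry 0.412. The tables argue against array scaling, since 42 of 42 members were higher after quantile normalisation. Another state of the culture's time course stays open (r = 0.19 over features with untreated 24 h minus 0 h), as does an effect of migration. At 0 h the fMLP with PMN array was already above the untreated one (36 of 42 members, median 0.24), so part or all of the 0.22 may have been present before.

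Time pairs the arrays, and splits that part fewer pairs than the real one are fits of another form, so the bound set beforehand over all splits does not decide. For migration against fMLP, 100 splits of the 10 arrays were counted. The real split called 0 features, which all 100 match by necessity, and the highest other called 17. Of the 100, 1, the real split, reached 4241 features at an unadjusted p under 0.05 (highest other 3871). The 14 that part all pairs are too few for a share under 0.05, with a highest other of 2456. At least 4 lists were called in 66 of the 100 (highest other 13) and in 10 of the 14 (highest other 11), so chance cannot be excluded for the lists.

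For anti-CD47 against migration there were 35 splits. As many features as the real 1 were called in 5 (highest other 1). As many lists as the real 5 were called in 17 (highest other 8), and in 5 of the 8 splits that part all pairs, so chance cannot be excluded for the lists. The 4273 features at an unadjusted p under 0.05 were reached in 1 split, the real one (highest other 2431), as were the 410 called after normexp (1 split, highest other 28). For the counts of features, those 8 splits are too few for a share under 0.05, with highest others of 0 called features, 1493 at p under 0.05, 0 after normexp and 7 lists, and 3 of the 35 could not be estimated. For anti-CD47 against fMLP the splits are too few for a share under 0.05: all 10 gave at least the real 0, with a highest other of 1.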

How the results depend on the processing

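The alternatives with only the 90 min, 4 h and 24 h pairs and without the features that set the 48 and 72 h arrays apart were chosen only after the result was seen. Of 192 alternatives for counts of features or lists, 114 stayed within 1.5 times the main count. Of 3634 for single genes, 3288 were labelled the same. For matched times this meant that sign and call were kept, and for single times a move of at most 0.35 without a change of sign. All named genes of the matched-time comparisons except CD69 were uncalled in the main fits. For these, staying uncalled with the same sign was enough, so the share says little about their robustness. Unless stated, the cause of a change was not tested. Migration against fMLP called 0 features by limma (4241 at an unadjusted p under 0.05), 287 with trend and robust options and 13 in 1 additive fit over 17 arrays. Anti-CD47 against migration called 1, but 410 with normexp, 2 with quantile normalisation, 0 without a filter (CD69 adjusted p 0.0589), 131 with features above background on every array (which leaves CD69 out of the fit), 873 with trend and robust, 1407 in the additive fit, 536 with the 0 h pair added, 0 without the 48 and 72 h features (4121 at p under 0.05; this removes CD69, the only call) and 0 to 0 with 1 time left out. Fewer matched times leave fewer degrees of freedom. With trend and robust options fMLP against untreated called 13 and migration against untreated 7. Anti-CD47 against fMLP, 0 in limma, called 123 with normexp, 1 with every array above background, 146 with trend and robust, 1275 in the additive fit, 3 without the 90 min pair and 0 to 3 with 1 time left out. Early against late called 1 after quantile normalisation. In the comparisons over 2 times no time could be left out, because 1 pair leaves no residual degrees of freedom.

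Quantile normalisation moved the split of features at p under 0.05 for anti-CD47 against migration from 2430 higher and 1843 lower to 2009 and 2310. Lists called in migration against fMLP went from 4 to 2 with the deposited series values, without a filter, with the mean over probes and without the 90 min pair, to 2 to 9 with 1 time left out, to 11 with the 90 min, 4 h and 24 h pairs, and to 0 with an estimated correlation and 0 with fry. In anti-CD47 against migration the 5 became 3 to 5 with 1 time left out, 0 with an estimated correlation and 0 with fry, and in fMLP against untreated the 1 became 0 and 0.

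Features past the size rule depended on background correction and on the threshold. With normexp, no filter, every array above background, 1.5-fold, 3-fold, fMLP alone and untreated alone, the 276 for migration at 4 h became 73, 902, 173, 1139, 71, 504 and 560, and the 197 at 24 h became 30, 661, 75, 584, 80, 439 and 389. For anti-CD47 the 374 at 4 h became 88 with normexp, 1106 without a filter, 1517 at 1.5-fold, 113 at 3-fold, 697 against fMLP alone and 661 against untreated alone (178 higher and 199 lower after quantile normalisation), and the 468 at 24 h became 92, 1096, 1871, 122, 988 and 760, and 272 with every array above background. At 0 h, with normexp, no filter, 1.5-fold and 3-fold, the 147 of the untreated array became 21, 582, 689 and 42, the 133 of migration 11, 506, 477 and 50 (55 with every array above background, 399 against untreated alone) and the 262 of anti-CD47 60, 624, 861 and 80.

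Signs reversed for ABCC2 with the mean over probes (−0.08), and in migration against fMLP for MX2, MX1, CXCL10 and OAS2 without 72 h (with 1 time left out −0.05 to 0.68, −0.02 to 0.6, −0.17 to 0.6 and −0.06 to 0.6) and with the 90 min, 4 h and 24 h pairs (−0.08, −0.06, −0.09 and −0.1), so their positive mean rests on 72 h. For anti-CD47 they reversed for CD163 without 24 h (−0.65 to 0.06 with 1 time left out), MS4A7 with the 0 h pair (0.18) and MT1L with the mean over probes (0.1). List medians at single times reversed with the mean over probes for erythrocyte and platelet in migration against fMLP at 4 h (−0.06), unfolded protein in anti-CD47 against migration at 4 h (0.04) and CD47 axis in fMLP against untreated at 4 h (0.18), without a filter for monocyte macrophage in migration against fMLP at 24 h (−0.02), and with quantile normalisation for interferon in fMLP against untreated at 24 h (−0.02).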

Other observations

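The observations in this part were chosen only after the result was seen, and no p is given for them. Several gene groups differed between arrays of different times, which also lie on different slides with 1 array per treatment and time. With fMLP alone, the median difference of cell cycle genes from 90 min was 0.77 at 24 h and 1.43 over 48 and 72 h, and that of sterol synthesis genes 0.46 and 1.4. Interferon response genes went from 0.85 at 24 h to −1.24 over 48 and 72 h, and metallothionein genes from 1.03 to −1.63. In untreated cells at 24 h against 0 h the interferon and metallothionein medians were 0.96 and 1.03.

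Among the 168 named genes that set the 48 and 72 h arrays apart, with and without PMN, some picked by eye and not by a list or a test are given here. Class II genes were lower there than on the untreated and fMLP arrays from 90 min to 24 h: HLA-DRA by a difference of −3.60, HLA-DPA1 −3.90, HLA-DQA1 −3.61 and the invariant chain gene CD74 −2.56. The acute phase genes SAA1 and SAA2 stood at −3.83 and −2.83, complement C3 at −2.54 and the cytokine gene IL6 at −3.18. CA9, a carbonic anhydrase induced by low oxygen, was higher by 4.10, and the chemokine receptor gene ACKR3 was well above background on all 4 of these arrays and 0 of the 5 earlier ones. On the 0 h anti-CD47 array most of these stood on the same side of the fMLP with PMN array (HLA-DQA1 −1.10, IL6 −1.26), while CA9 stood at 0.30 against that array and −0.09 against the untreated one.

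In the comparison of anti-CD47 with migration, 166 of 215 features of this set (77.2%) had an unadjusted p under 0.05, compared with 4107 of 23177 others (17.7%). The 48 and 72 h arrays share 1 slide that holds no earlier array, so time and slide cannot be separated there. HBB stood at −5.67 and −5.61 on the 0 h arrays of untreated cells and of fMLP with PMN, and at −3.06 to −1.87 on the later untreated and fMLP arrays, which had no PMN.

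Among genes above background on at least 4 of 6 arrays from 90 min to 4 h with migration and on none of the 10 arrays without it, 6 were found: AIF1 and FCGR3A, both known from macrophages, the myeloid receptor gene LILRB3, and GSG1L, FAT2 and XKR3. Of 1000 random choices of 6 of 16 arrays, 49 gave as many genes or more (mean 1.66, highest 75).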
